A study of Drosophila melanogaster with 3 samples.

How the data were processed

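Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of 0 to 24 h, of mixed sex. They came from transgenic flies that expressed CG1647 fused to GFP. Per the labels, the fusion protein was pulled down with an antibody against GFP, chromatin was sheared by sonication and fragments of 200 to 800 bp were used. There were 3 biological replicates of 1 group. The labels name no second condition, so no comparison between conditions could be made, and the comparisons here are between replicates, between peak lists, and between peaks and the annotated genome.

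The authors deposited peak lists on 2 genome builds, dm6 and dm3, per the file headers and labels. For each build there was a candidate list per replicate, a candidate list for the pooled alignments of the 3 replicates, and a shorter list past a threshold of the irreproducible discovery rate (IDR), called the retained peaks here. Per the descriptions deposited with each library, the candidate lists were made as input for IDR against a control alignment and hold background as well as peaks. The aligner, the peak caller, the IDR threshold and the tool versions are not given in the sources used here. Each peak has a signal value, which the authors' peak caller gave and which is never negative. The deposited lists also hold the −log10 of each peak's q-value and the position of its summit. The score column held 0 and the p column held -1 in every list, so neither was used. Signal was used to describe, rank or filter peaks within a list. Its ranks were also compared between promoter and other peaks and correlated between replicates. Read counts were not used here, so the sequencing depth of each replicate is unknown and no depth-based precision is given; intervals cover counting error over peaks or genes only, and neighbouring peaks and genes are not independent.

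Positions were taken from the dm6 lists. The gene annotation was Ensembl release 115 of the same assembly (release 6, FlyBase genes), and the sequence came from the RefSeq copy of it. The analysis covered the 6 arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were compared only with each other, except that the dm3 count of retained peaks per arm was set against the dm6 shares of genes, and no coordinates were converted. A gene was called bound where a retained summit lay within 500 bp of the 5′ end of any of its transcripts (TSS). Unretained candidates are the peaks of the pooled list that overlap no retained peak. The 29 gene lists, the 14 motifs, the tests and most alternatives were fixed before the data were examined. Every listed symbol was found, 9 of them under a newer name. The list of cytochromes P450 was defined by symbol and took in Cyp1, a cyclophilin. MicroRNA genes were taken by their symbols because the annotation gives them no class of their own.

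Replicate lists of unequal length were brought to the 3123 peaks with the highest signal, the length of the retained list, and a peak counted as found where at least 1 bp overlapped. Chance levels came from 1000 relocations of the peaks within their arm, whose smallest possible p is 0.000999. The relocation test of promoters was one-sided and all other tests were two-sided. Gene lists, head-to-head genes and retained against unretained candidates were tested with Fisher's exact test, arms with an exact binomial test, and motifs with an exact McNemar test between the 200 bp around a summit and a 200 bp window centred 500 bp away on a randomly drawn side. The ratio of a motif or word is the number of peaks with it in the summit window only over the number with it in the control window only, with 0.5 added to each, and so is not the quotient of the shares. Signal ranks were compared with a permutation test of 100000 resamples. The 8-base words were ranked on arms 2L and 2R, and the 20 best were tested on the other arms. P-values were adjusted by the Benjamini-Hochberg method within each family (29 lists, 14 motifs, 20 words, 6 arms or 4 noncoding classes), with a threshold of 0.05. Against the background of genes with a candidate peak, only lists with at least 5 such members were tested and adjusted. Intervals of shares are exact Clopper-Pearson 95% intervals, and those of odds ratios are Woolf intervals with 0.5 added to each count.

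The genes named were set by a rule. It took the gene nearest to each of the 25 retained peaks with the highest signal, with every gene whose TSS lay within 500 bp of that summit. From each fixed list it took up to 4 bound members by signal and up to 2 unbound members in alphabetical order, and it added CG1647. Names outside the rule are marked where they occur.

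Alternatives were the 1561 retained peaks with the highest signal, leaving out each replicate in turn (keeping retained peaks found in both others), other overlaps and list lengths, distances of 200 and 1000 bp to a TSS, peak midpoints, other TSS sets and backgrounds, other windows and controls, and the dm3 lists. Midpoints lay close to summits, with 94.2% of retained peaks at the same width of 390 bp, so they hardly test the choice of summits. Chosen after seeing the data were the values of each replicate's own 3123 best peaks, joining overlapping peaks, thinning list members to 1 per 10 kb, windows at unbound promoters placed as the summits lie, the alternatives for coding exons, and the comparison of words between peaks near and far from a TSS. The tests were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. An exploratory run on the real lists came before the tests were tried on simulated data. In simulated lists of 100 genes with 50% bound, 100% were called over 13945 genes, against 0.370% of unchanged lists. Binding was drawn gene by gene, so these shares do not cover the smaller fixed lists or genes that share a summit. No word was called among 3123 simulated windows with none planted, and a word planted in 5% of them was called. Summit and control windows of that simulation both lay at random positions. It therefore does not cover the difference in GC content between the real windows.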

Results

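Binding of the CG1647-GFP fusion protein was measured by ChIP-seq in 3 replicates of whole embryos aged 0 to 24 h, which hold every embryonic tissue. The authors' retained list on dm6 held 3123 peaks with a median width of 390 bp that covered 1.17 Mb. Its signal values had a median of 189 and ran from 126 to 2899. The candidate lists held 30000 peaks in replicate 1, 17977 in replicate 2, 30000 in replicate 3 and 19204 for the pooled alignments. All 3123 retained peaks were the 3123 with the highest signal in the pooled list, or 16.3% of it. Of the retained peaks, 197 overlapped another, and joining these left 3024 regions. The dm3 retained list held 2932 peaks. Both replicate lists of 30000 hold the same round number, as a fixed upper limit on list length would give, so list lengths are no measure of how much was bound. Sequencing depth is unknown.

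The 3 replicates were compared by the binding sites they shared. Among the 3123 best-ranked peaks of each replicate, the retained peaks were found at 79.4% in replicate 1, 85.3% in replicate 2 and 81.3% in replicate 3, a mean of 82.0% ± 3.01 (SD, n = 3). In all 3 replicates 1824 peaks were found (58.4%, 95% interval 56.7 to 60.1). Another 931 were found in exactly 2 replicates, 352 in exactly 1 and 16 in 0. With the list split by signal into 10 parts, 100% of the highest part was found in all 3 replicates, 62.2% of part 6 and 4.17% of the lowest. These shares are partly built in, because the retained list and its signal come from the pooled reads of the same 3 replicates. The list holds exactly the 3123 pooled peaks with the highest signal, so no peak above that cut was left out as irreproducible. In the full candidate lists, 99.6%, 99.5% and 99.9% of retained peaks had an overlapping peak in replicates 1, 2 and 3. Compared without the retained list, pairs of replicates shared 70.0% (1 and 2), 70.1% (1 and 3) and 71.1% (2 and 3) of their best peaks, where relocation gave at most 2.53%. Spearman's rho of the signal for these pairs was 0.617, 0.654 and 0.611. It was taken across the 3094, 3105 and 3103 retained peaks with a candidate peak in both replicates. It therefore covers only peaks of high pooled signal. Peaks are not independent replicates, so no p is given.

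**Figure D1:**
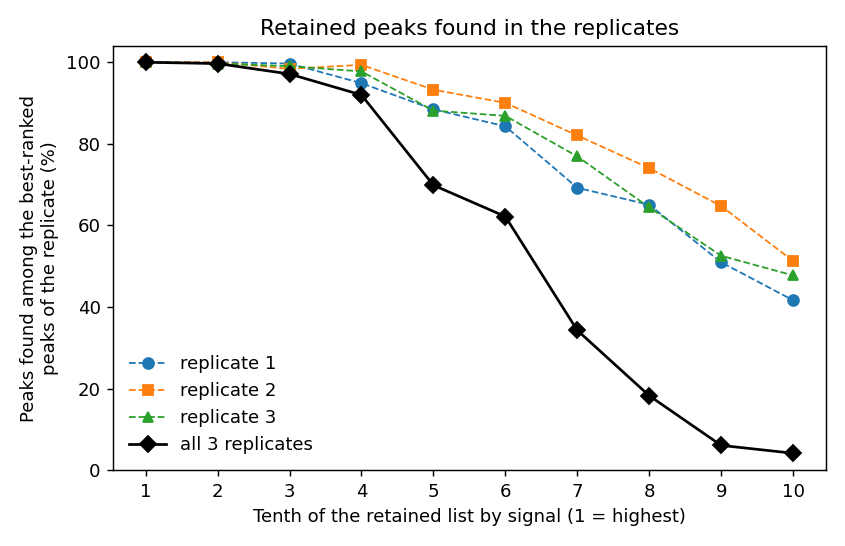
Share of retained peaks (%) found among the 3123 best-ranked peaks of each replicate and of all 3, for 10 parts of the retained list in order of signal. Support in all 3 replicates fell from 100% in the highest part to 4.17% in the lowest, where single replicates held 41.7% to 51.3%.

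The 25 peaks with the highest signal were found in the best-ranked peaks of every replicate, none below rank 60 in any of them. The highest lay upstream of CG14100 (FBgn0036889), with its summit at 19590625 on 3L, 101 bp from the TSS, a signal of 2899 and ranks 2, 1 and 1 in replicates 1, 2 and 3. The next was at the promoter of Ugalt, a UDP-galactose transporter gene (X, summit 2703880, signal 2622, 28 bp from the TSS). Rank 3 was an intronic summit on 2L at 481093, 1405 bp from the nearest TSS, that of cbt, a zinc finger transcription factor gene (signal 2470). An intron of CG11050 (2L, summit 6612719, signal 2062) and ph-p followed, the latter a Polycomb group gene on X with a summit at 2137322 and a signal of 1835.

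Of these 25 peaks, 18 had a TSS within 500 bp, and 8 lay between or near 2 or more genes. Single summits served both Chro, a chromodomain protein gene, and Ssl1, a TFIIH subunit gene (3L, summit 22878878, signal 1711). The same held for Tcs5 and CHMP2B (3L, 5139506, signal 1627), Art3 and mRpS10 (3R, 15229523, signal 1412), CG9147 and Fbw5 (2L, 6066083, signal 1302), CenG1A and mRpS23 (2L, 13835456, signal 1291), Shc and Atat (3L, 9426886, signal 1198), mRpL23 and CG9004 (3L, 2373587, signal 1174), and CG7601 and CIA30 (3R, 29736844, signal 1154). Other promoter summits in this group were those of px, PNPase, CG1888, mRpL41, GstE13, CG18549 and larp, with signals of 1770, 1720, 1557, 1268, 1240, 1202 and 1155. Away from promoters lay summits in introns of Lk6 (3R, 11761055), CG32772 (X, 4910378) and CG9663 (2L, 3302184). The summit nearest to CG4004 fell in a noncoding exon 5115 bp from its TSS, and that nearest to tara, a trithorax group gene, was intergenic at 3170 bp.

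Where in genes the protein was found was asked next. Promoters of protein-coding genes held 1724 of the 3123 retained summits (55.2%, 95% interval 53.4 to 57.0). Relocated summits gave 11.5% and at most 13.4%, a 4.81-fold difference (permutation by relocation, p = 0.000999, the smallest that the relocations can give). With relocation only within 20 kb of each summit the difference was 3.04-fold. Each replicate's own best peaks gave 54.5% ± 1.68 (SD, n = 3). Promoter summits lay at a median of -78.5 bp from the nearest TSS (negative is upstream), and 82.0% of them were upstream. Coding exons outside promoters held 9 summits (0.288%, 95% interval 0.132 to 0.546), where relocation gave 13.9% and never less than 11.8%. Their share was 0.833% ± 0.693 (SD, n = 3) over the replicates' own best peaks, with 1.60% in replicate 1, 0.256% in replicate 2 and 0.640% in replicate 3. Summits in 3′ UTRs (0.672% against 4.50%), introns (30.3% against 39.8%) and intergenic DNA (11.4% against 28.0%) were also below every relocation. The classes exclude each other and promoters took precedence, so the promoter excess by itself lowers the other shares. Among summits outside promoters, the part in introns was larger than after relocation. Noncoding exons (1.60% against 1.54%) and 5′ UTRs (0.544% against 0.790%) were within the range of the relocations. More than 5 kb from any TSS lay 472 summits (15.1%).

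**Figure D2:**
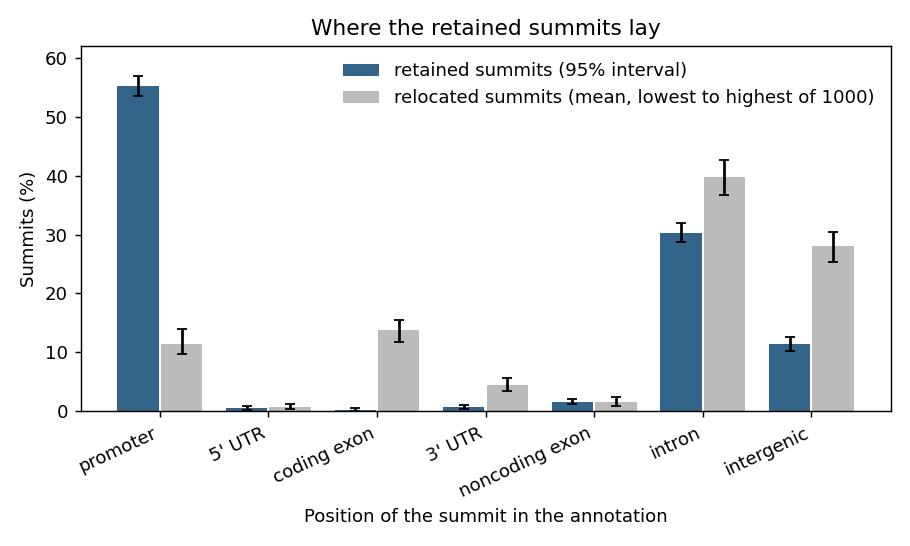
Share of retained summits (%) in each part of the annotation with its 95% interval, beside the mean share of relocated summits with the lowest and highest of 1000 relocations. Promoters held 55.2% against 11.5%, and coding exons 0.288% against 13.9%.

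Retained peaks also differed from the candidates of the pooled list that overlapped no retained peak. Of 15633 such unretained candidates 4388 lay at promoters (28.1%), against 55.2% of retained peaks (odds ratio 3.16, 95% interval 2.92 to 3.42, Fisher's exact p = 7.16e-181). Coding exons held 2966 of the unretained candidates (19.0%) and 0.288% of the retained peaks (odds ratio 0.0123, 95% interval 0.00688 to 0.0247, exact p = 6.66e-239), a test chosen after the retained share was seen. Within the retained list, promoter peaks had a median signal percentile of 51.9 and other peaks 48.0 (difference 3.91 percentile points, permutation p = 0.0276). That difference in signal was not past the threshold without replicate 1 (0.621, permutation p = 0.788) or without replicate 2 (3.39, p = 0.121), and was larger without replicate 3 (6.13, p = 0.00419).

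Which genes were bound was tested with lists of genes that share a function. Of 13945 protein-coding genes 2266 were bound (16.2%). Genes for cytoplasmic ribosomal proteins, the protein part of the ribosome, were bound most often of the 29 lists: 56 of 92, or 60.9% (95% interval 50.1 to 70.9; odds ratio 8.20, 5.36 to 12.4; adjusted exact p = 1.08e-20). Over the replicates' own best peaks their share was 58.7% ± 7.61 (SD, n = 3), against 15.8% ± 0.991 of all genes. Against the background of genes with a candidate peak the odds ratio was 4.06 (adjusted exact p = 5.62e-08). RpL7 (signal 785), RpS27 (779), RpL23A (622) and RpL34b (558) had the highest signals among them, with summits 36, 24, 109 and 70 bp from a TSS, while RpL10 and RpL10Aa were not bound.

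Genes of other large cellular machines were not bound to that degree. Mitochondrial ribosomal protein genes were bound at 20 of 73 (27.4%, odds ratio 1.95, adjusted exact p = 0.0508), short of the threshold, although mRpS10, mRpS23, mRpL41 and mRpL23 were all among the 25 strongest peaks. Without replicate 1 that list passed it (odds ratio 2.34, adjusted exact p = 0.0170). Oxidative phosphorylation genes were bound at 14 of 80 (17.5%, odds ratio 1.09, 95% interval 0.636 to 1.99), among them ND-ASHI (signal 483) and ND-MWFE (376). Proteasome subunit genes were bound at 7 of 48 (14.6%), led by Rpn5 (375) and Rpn13 (250). Translation initiation factor genes gave 9 of 44 (20.5%), led by eIF6 (1033) and eIF1 (430), and heat shock protein genes 3 of 19 (15.8%), namely Hsp27 (655), Hsp83 (473) and Hsp26 (208). None of these 4 lists passed the threshold.

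Genes for chromatin regulators were bound more often than other genes in 3 lists. Polycomb group genes, which keep developmental genes silent, were bound at 9 of 19 (47.4%, odds ratio 4.65, adjusted exact p = 0.00730), with ph-p (signal 1835), E(z) (247), Su(z)12 (229) and Sfmbt (190) highest. Trithorax group genes, which act against that silencing, were bound at 8 of 16 (odds ratio 5.17, adjusted exact p = 0.00747), led by brm (446), Trl (297), fs(1)h (296) and Bap60 (237). Insulator and boundary protein genes were bound at 7 of 17 (41.2%, odds ratio 3.62, adjusted exact p = 0.0463), led by Chro (1711), Cp190 (435), pzg (287) and Dref (231). Over the replicates' own best peaks the shares were 42.1% ± 5.26, 45.8% ± 3.61 and 39.2% ± 3.40 (SD, n = 3). Against the background of genes with a candidate peak the 3 calls were lost, with odds ratios of 2.57 (adjusted exact p = 0.273) for the Polycomb group, 4.57 (0.124) for the trithorax group and 1.71 (0.853) for insulator genes. The Polycomb group call was also lost without replicate 1 (odds ratio 2.54, adjusted exact p = 0.243) and without replicate 3 (2.84, 0.193), the trithorax group call without replicate 2 (3.69, 0.102), and the insulator call without replicate 2 (3.38, 0.116) and at 1000 bp (3.05, 0.0970). All 3 were lost in the 1561 peaks with the highest signal, at odds ratios of 2.73 (adjusted exact p = 0.267), 4.66 (0.0513) and 4.27 (0.0578).

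Genes of 4 large families were rarely called bound. Chemosensory receptor genes, which encode odour and taste receptors, were bound at 1 of 179 (0.559%, adjusted exact p = 1.36e-11), the carbon dioxide receptor gene Gr63a (signal 135). Cuticular protein genes were bound at 0 of 70, which allows up to 5.13% (adjusted exact p = 4.07e-05), and cytochromes P450 at 1 of 85, Cyp6u1 (signal 422; adjusted p = 5.56e-05). Replication-dependent histone genes were bound at 0 of 111 (adjusted exact p = 5.21e-08). Their near-identical copies lie in 1 cluster and none had even a candidate peak, so a lack of binding there cannot be told from a lack of measurement. The P450 odds ratio of 0.0609 rose to 0.0958 without replicate 2 and 0.0939 without replicate 3, and the chemosensory odds ratio of 0.0285 fell to 0 whichever replicate was left out. Thinned to 1 member per 10 kb, the histone list kept an odds ratio of 0 but lost its call (adjusted exact p = 0.525). Against genes with a candidate peak, the cuticular list, at 10 members, kept an odds ratio of 0 without a call (adjusted exact p = 0.118), the chemosensory list, at 11, moved to 0.170 (0.224), and the histone list could not be tested.

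Developmental and tissue lists did not differ from other genes by the test. Hox genes were bound at 0 of 8 and pair-rule and segment polarity genes and dorsoventral patterning genes at 0 of 17 each. Gap and maternal patterning genes gave 2 of 14, bcd (signal 229) and nanos (212), and the Notch pathway 5 of 16 (31.2%), led by N (188) and Su(H) (185). Among tissue markers the bound genes were elav of 17 nervous system genes (signal 563), sls (296) and Mef2 (176) of 15 muscle genes, nanos and gcl of 12 germline genes, fkh (442) and Mtp (255) of 11 gut and fat body genes, and bnl of 8 tracheal genes. Of 10 hemocyte and 8 epidermal markers 0 were bound. Cell cycle genes gave 5 of 23, ecdysone response genes 3 of 12, circadian clock genes 3 of 10 and dosage compensation genes 1 of 6, and none of these lists passed the threshold. The small lists leave wide intervals, up to 36.9% for 0 of 8.

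**Figure D3:**
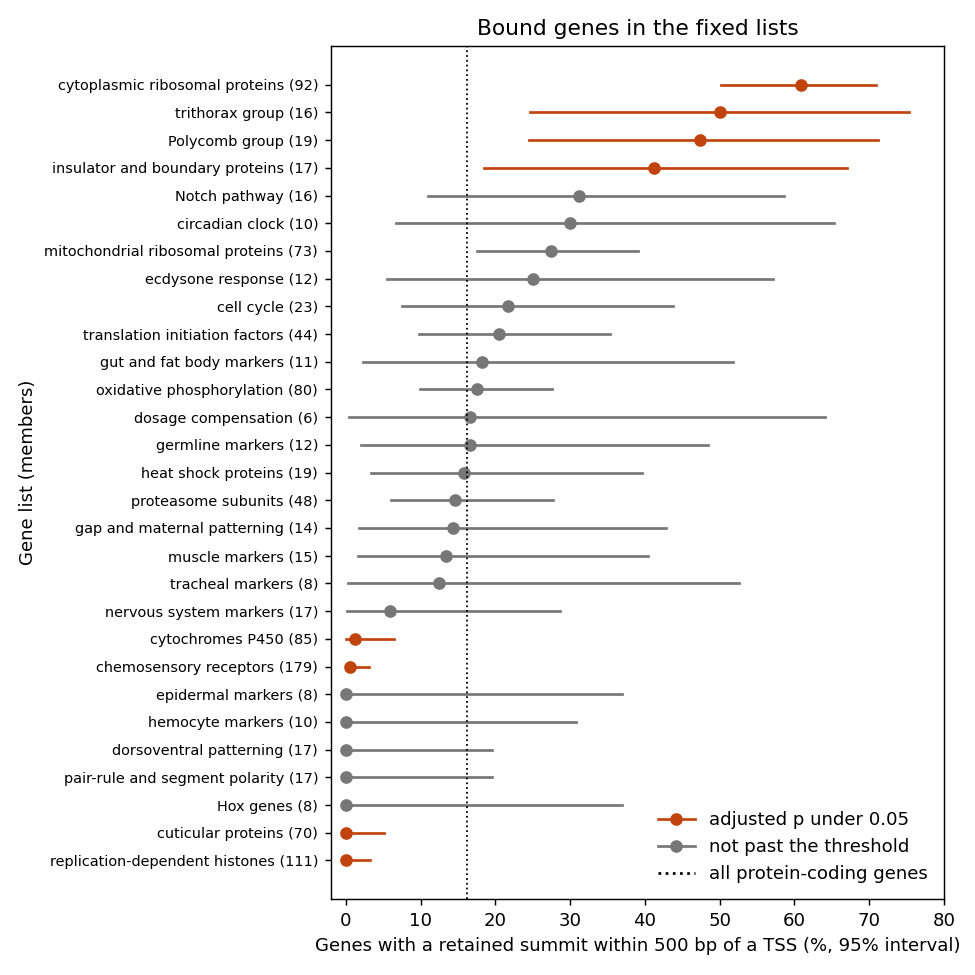
Share of genes (%) with a retained summit within 500 bp of a TSS in each of the 29 fixed lists (members in brackets), with exact 95% intervals; the dotted line is the 16.2% of all protein-coding genes. Cytoplasmic ribosomal protein genes stood highest at 60.9%. Lists of 4 families lay between 0 and 1.18%, among them the histone genes, which had no candidate peak.

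Small noncoding RNA genes were tested by class. Small nuclear RNA genes, most of which encode RNAs of the spliceosome, had a retained summit within 500 bp at 8 of 32, where relocation gave 2.83% (8.83-fold, adjusted permutation p = 0.00799). That call was lost without replicate 1 (5.10-fold, adjusted permutation p = 0.216). Genes for tRNAs (10 of 290), snoRNAs (11 of 269) and microRNAs (7 of 260) did not pass the threshold, with adjusted permutation p of 0.679, 0.667 and 0.919. Within 1000 bp the snoRNA genes passed it (3.56-fold against 1.66-fold within 500 bp, adjusted permutation p = 0.00799).

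Genes that start head to head with a neighbour on the other strand were bound more often. Of 3483 such genes 1146 were bound (32.9%), against 1120 of 10462 others (10.7%; odds ratio 4.09, 95% interval 3.72 to 4.49, Fisher's exact p = 2.07e-185). Over the replicates' own best peaks, 49.1% ± 2.91 of bound genes and 20.4% ± 0.858 of unbound genes were head to head (SD, n = 3). As in the pair of Chro and Ssl1, 1 summit can count for 2 genes, so this p is too small. In 100 relocations the odds ratio averaged 0.929 and reached at most 1.29. These relocations place summits anywhere on the arm and not at promoters. They cannot show how much of the odds ratio comes from summits that count for 2 genes.

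Along the chromosomes, the share of peaks was close to the share of genes. The X chromosome held 545 peaks, 1.11 times its share of genes (adjusted exact p = 0.0233), 3L held 670 (1.09 times, adjusted p = 0.0233), 2R 580 (0.908 times, adjusted p = 0.0233) and the small chromosome 4 only 9 (0.502 times, adjusted p = 0.0480). Arms 2L (0.981 times) and 3R (0.959 times) did not pass the threshold. None of the 4 calls held without replicate 1 or without replicate 2, or in the dm3 list. In dm3 X was at 1.10, 3L at 1.09, 2R at 0.926 and chromosome 4 at 0.535 times, and without replicate 1 they were at 1.12, 1.05, 0.938 and 0.481 times. Without replicate 2 they were at 1.10, 1.03, 0.971 and 0.583 times, and without replicate 3 only the X call held (1.20 times). In the 1561 peaks with the highest signal 3L turned to 0.969 times and chromosome 4 was at 0.782 times without a call. Against arm length in place of genes X turned to 0.992, with 2R at 0.983 and 3L at 1.02 times, while chromosome 4 fell to 0.286 times and kept its call (adjusted exact p = 3.41e-05).

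Sequence at the summits was compared with sequence 500 bp away. Each ratio is of peaks with the motif in the summit window only to peaks with it in the control window only (0.5 added to each), not of the shares. The DNA replication-related element (DRE, TATCGATA), bound by Dref and BEAF-32, was found at 153 of 3123 summits (4.90%) and in 19 control windows (0.608%; ratio 8.24, exact McNemar adjusted p = 9.15e-27). Core promoter motif 7 was found at 8.13% against 2.11% (ratio 4.21, adjusted exact p = 1.44e-27), and the CTCF core, the site of the insulator protein CTCF, at 2.50% against 0.544% (ratio 4.49, adjusted p = 5.75e-10). Over the replicates' own best peaks the DRE was at 4.74% ± 0.285, motif 7 at 7.54% ± 0.911 and the CTCF core at 2.47% ± 0.305 of summits (SD, n = 3). The short CGATA word (32.7% against 21.9%), motif 1 (1.73% against 0.224%), motif 6 (0.640% against 5 control windows), the promoter E-box (1.76% against 0.608%), the su(Hw) core (0.640% against 0.224%) and the TATA box (11.5% against 7.40%) were also higher at summits, and the CA repeat was lower (3.91% against 7.52%). The GAGA repeat, Zelda, initiator and CLAMP motifs did not pass the threshold. The GAGA repeat was called lower at summits without replicate 3 (ratio 0.668, adjusted exact p = 0.00989) and in 100 bp windows (0.436, 0.000111), CLAMP in 100 bp windows (0.371, 0.0456) and Zelda with overlapping peaks joined (0.692, 0.0325). Leaving out 1 replicate moved some ratios: that of motif 1 went from 7.27 to 3.35 without replicate 1, that of motif 6 from 3.73 to 5.80 without replicate 1 and 2.82 without replicate 2 (adjusted exact p = 0.0579), and that of su(Hw) from 2.73 to 5.80 without replicate 2. The su(Hw) call was lost without replicate 1 (2.38, adjusted exact p = 0.0914) and without replicate 3 (2.07, 0.170), with control windows 1000 bp away (1.52, 0.415), in the 1561 peaks with the highest signal (2.27, 0.183) and with overlapping peaks joined (2.16, 0.0782), as well as against promoters of unbound genes (odds ratio 2.18, 0.0826). Mean GC content was 37.8% at summits and 43.7% in control windows.

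Part of this contrast is that of promoters against other DNA, so promoter summits were also set against promoters of unbound genes. Motif 7 (13.4% against 5.86%, odds ratio 2.49, adjusted exact p = 3.66e-25), the CTCF core (1.80% against 0.454%, odds ratio 4.02, adjusted p = 8.42e-08) and CGATA (odds ratio 1.17, adjusted p = 0.00819) stayed higher. The DRE was at 8.58% of promoter summits and 7.02% of unbound promoters (odds ratio 1.24, adjusted exact p = 0.0508). The TATA box was lower at bound promoters (odds ratio 0.750, adjusted exact p = 0.000796) and so was the initiator (0.446, adjusted p = 4.20e-36), which lies at the TSS itself. With unbound windows placed as far from the TSS as the summits, the DRE was higher at bound promoters (8.58% against 4.61%, odds ratio 1.94, adjusted exact p = 2.73e-10). With those windows the promoter E-box was also higher (odds ratio 1.56, adjusted exact p = 0.0140), against 1.03 without a call at the TSS. The initiator stayed lower (0.635, adjusted exact p = 2.31e-11). Motif 7 stayed higher (3.46, adjusted exact p = 2.08e-41), and motif 1 was at 1.32 without a call.

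**Figure D4:**
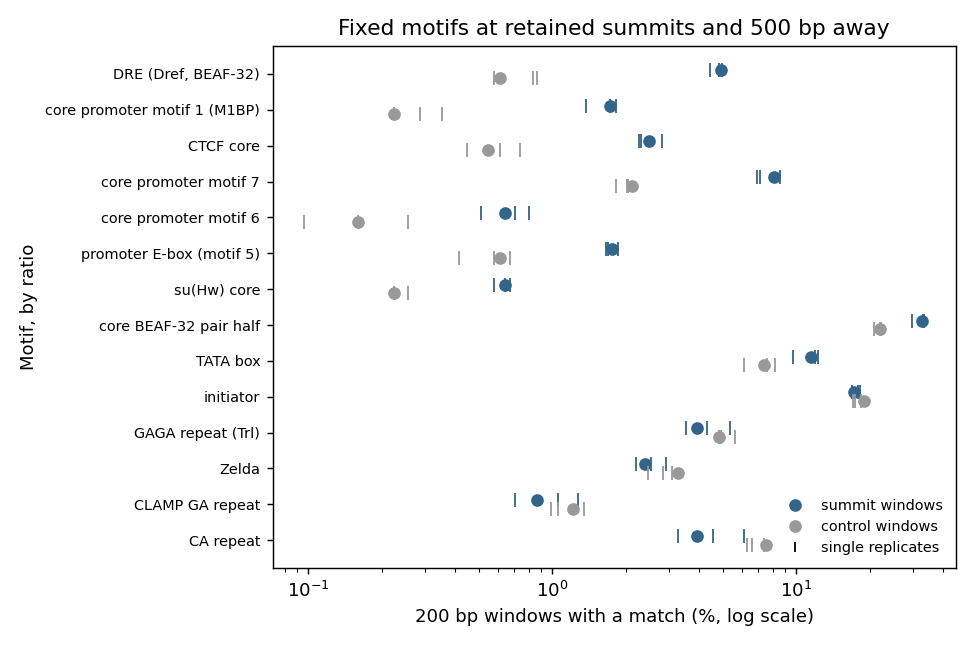
Share of 200 bp windows (%, log scale) with a match to each of the 14 fixed motifs at retained summits and in control windows centred 500 bp away, with each replicate's own best peaks as ticks. The DRE was found at 4.90% of summits and 0.608% of control windows, and the CA repeat at 3.91% and 7.52%.

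A search over all 8-base words on arms 2L and 2R (1164 peaks) gave 20 words, all of which were higher at the summits of the other arms (1959 peaks; ratios are again of summit-only to control-only peaks). Among them, 7 held the DRE core ATCGA or TCGAT: ATCGATAG was at 4.90% of summits and 0.613% of control windows (ratio 8.30, exact McNemar adjusted p = 1.55e-16), and TATCGATA at 4.54% against 0.613%. Words unlike the DRE were CAACACTG (4.59% against 0.562%, ratio 9.32, adjusted exact p = 2.00e-16), CACTGAGA (3.22% against 0.255%, ratio 11.5, adjusted p = 3.06e-13) and CCACTGTA (2.91% against 0.664%, ratio 4.26, adjusted p = 1.58e-07). Words of A and T, such as TTAAAAAA (9.39% against 4.80%), made up most of the rest. Mean GC content was lower in summit windows than in control windows (37.8% against 43.7%), and the word test did not correct for it. With the search repeated on peaks found in the other replicates, the ratio of CACTGAGA was 5.77 without replicate 1, 8.33 without replicate 2 and 7.73 without replicate 3, and that of ATCGATAG was 12.5, 7.12 and 4.56.

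The promoter of CG1647 itself, the gene that was tagged (FBgn0039602, 3R, 28820221 to 28824508, plus strand), held 2 retained peaks. Their summits lay at -486 and -283 bp from the TSS, at 28819735 (signal 207, rank 1327) and 28819938 (signal 128, rank 3053), and the peaks overlapped. A candidate peak near this promoter ranked 2254 in replicate 1, 731 in replicate 2 and 2003 in replicate 3 at best. The flies were transgenic for this gene, and an effect of the transgene on reads at this locus was not tested. These peaks alone therefore do not show that the protein binds its own promoter.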

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

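Only the lists on the older build dm3 reached beyond the 6 chromosome arms. In its pooled candidate list, 17 of 15844 peaks lay on other sequences, data that no comparison above used. Their highest signal was 83.8, below the lowest signal in the dm3 retained list (130.5), their best rank was 6344, and 0 of them were retained.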

How the results depend on the processing

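Alternatives for coding exons, joined peaks, thinned lists, replicates' own peaks and offset promoter windows were chosen after seeing the data. The promoter excess (3.04-fold with relocation within 20 kb to 8.39-fold at 200 bp), retained against unretained candidates at promoters, the head-to-head excess and the coding exon share kept their direction in every alternative run. Of the 20 words that each search picked for itself, 16 to 20 passed. For the rest, the cause was not tested unless stated. By construction, the higher-signal part held 1561 peaks. Retained peaks found in every replicate were 51.9% at 50% overlap, 52.1% with summits within 100 bp, 98.9% in full lists, 86.9% in lists of 6246 peaks, 91.9% in the higher-signal part, and 67.1% to 69.6% in 2 replicates, where fewer need to hold the peak. Pairwise overlap (1 and 2, 1 and 3, 2 and 3) was 64.3%, 67.2% and 66.1% at 50% overlap, 64.1%, 63.5% and 65.0% with summits within 100 bp, 73.2%, 73.4% and 74.6% in lists of 1561 peaks, and 62.8%, 62.3% and 64.6% in lists of 6246. In the higher-signal part rho was 0.679 for replicates 1 and 3 and 0.583 for 2 and 3. The signal difference at promoters lost its call in the higher-signal part (4.07), at 200 bp (1.92), without replicate 1 (0.621) and without replicate 2 (3.39), and kept it without replicate 3 (6.13). Called gene lists fell from 8 to 5 in the higher-signal part (without the Polycomb, trithorax and insulator lists) and to 2 against genes with a candidate peak, where lists with under 5 such members, the histones among them, were not tested. Called noncoding classes were 0 to 1 without a replicate and 2 at 1000 bp, where snoRNA genes joined. Called arms fell from 4 to 2 in the higher-signal part, 1 by arm length, 0 for dm3 and 0 to 1 without a replicate; 3L turned to 0.969 in the higher-signal part and X to 0.992 by arm length. Against unbound promoters 5 motifs were called in place of 10; motif 1 (0.815), motif 6 (0.590), the TATA box (0.750) and the CA repeat (1.21) reversed, as did motif 6 (0.827), the TATA box (0.791) and the CA repeat (1.23) with offset windows. No paired analysis was possible because the labels give a single group. Unknown depth and the round length of 30000 in both longer replicate lists limit what full lists and list lengths show.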

Other observations

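The tests of words by distance to a TSS, of the CACTG core, of genes without a head-to-head neighbour, of coding exons and of CACTGAGA were chosen only after the results they bear on were seen. The oxidative phosphorylation list and the background of genes with a candidate peak were planned, but the use of the former to weigh the ribosomal list was chosen after its value was seen. Words at summits differed between the 1724 promoter peaks and the 1135 peaks over 1 kb from any TSS, by a search on arms 2L and 2R and a test on the others. On those, TATCGATA was at 8.11% of 1061 promoter peaks and 0.272% of 735 far peaks (Fisher's exact adjusted p = 2.75e-17), CAGCACTG at 4.90% and 0.544% (adjusted p = 3.21e-08), and GGTCACAC, part of motif 1, at 4.90% and 0.544%. Higher in far peaks were TACACTGA (5.03% against 1.51%, adjusted exact p = 0.000241), CACTGAGA (5.31% against 1.89%, adjusted p = 0.000604) and GAGAGAAA (5.71% against 2.36%, adjusted p = 0.00109). In all, 10 of 10 promoter words and 7 of 10 far words passed the threshold. Most far words that passed overlapped others by several bases, as TACACTGA and CACTGAGA do, and most promoter words held the DRE core. These counts are therefore not of independent sequences. The words were not compared with promoters of unbound genes, so part of the contrast can be that of promoters against other DNA. The DRE was at 8.58% of all promoter summits. At unbound promoters it was at 7.02% around the TSS and 4.61% in windows placed as the summits lie. An earlier look at all arms had shown some of these words, so the test arms are not fully independent.

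Several of these words share the bases CACTG, and the hypothesis was that this core marks the summits. On arms 3L, 3R, X and 4 CACTG was at 52.3% of 1959 summits and 29.7% of control windows (ratio of summit-only to control-only peaks 2.60, exact McNemar p = 4.86e-46). It ranked 3 of 512 words of 5 bases, behind AAATA and TAAAA. In 1741 peaks without a DRE or motif 7 match this ratio was 2.70 (52.6% against 29.0%, exact p = 3.01e-44). CACTG may be part of a sequence that CG1647 or a partner recognises, a hypothesis found and tested on the same peaks, since words with this core had been seen on all arms before the rank was taken.

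Cytoplasmic ribosomal protein genes were bound far more often than other genes. If promoters of much-used genes in general were bound, the oxidative phosphorylation list could be raised too. Its odds ratio was 1.09 with an upper bound of 1.99, below the lower bound of 5.36 for the ribosomal list. This comparison cannot decide the question, because it was chosen after the value was seen and gene use was not measured. Candidate peaks were at 41 of 80 oxidative phosphorylation genes and 80 of 92 ribosomal protein genes. Peaks of head-to-head neighbours would leave no excess among genes without such a neighbour, where 31 of 57 ribosomal protein genes were bound against 10.5% of others (odds ratio 10.2, 95% interval 6.04 to 17.1). Against genes with a candidate peak the odds ratio was 4.06, so a general enrichment of open promoters could account for part of the excess and remains open. The design gives no second condition, so no biological explanation was tested.

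Retained summits avoided coding exons (0.288%). Promoters took precedence over coding exons and held 55.2% of retained summits, which by itself lowers the coding share. No relocation held the promoter share, so this part was not separated. Base composition alone would bring summits relocated to windows of the same GC content down to 0.288%. They gave 5.77% and at least 4.29%, so GC content may account for part of the gap from 13.9% and not all of it. Nor did the peak calling leave coding exons out, since 19.0% of unretained candidates lay there. The reason why candidates in coding exons are weak remains open, and no biological explanation was tested.

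The word CACTGAGA was at 73 of 1135 far summits (6.43%) and in 5 control windows. Copies of a transposable element would put the word inside annotated elements, which held it in 0% of these peaks (95% interval 0 to 4.93). How many far summits lay in any annotated element was not counted, and how the aligner treated repeated sequence is unknown. The 0% therefore cannot decide the question, and unannotated repeats stay open too. Base composition remains open: 99.6% of 1679 reordered words had a lower ratio of summit-only to control-only peaks than its 13.4, with 29 the highest, but the word had been picked for its enrichment on peaks that this ranking includes. No biological explanation was tested.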
